A study of Caenorhabditis elegans with 2 samples.

How the data were processed

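Chromatin immunoprecipitation with sequencing was performed on whole L4 larvae of strain RW12267, in which the vab-7 gene carries an insertion that adds EGFP to its protein, per the labels. Chromatin was sheared by sonication and precipitated with an antibody against GFP. There were 2 samples, biological replicates 1 and 2 of 1 group. The labels number them as biological replicates, and nothing more is said of how the cultures were separated. A control experiment is named in the labels and was not analysed here.

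The deposited files are 8 lists of peaks on ce11, the build the labels name. Each replicate has a list of peaks ranked by the irreproducible discovery rate (IDR) and a thresholded list. The series has a thresholded list, a conservative thresholded list and 2 ranked lists, 1 of which compares the replicates. Peaks were therefore called both per replicate and over both replicates. The peak caller, aligner, read depth and control handling are not given in the sources used here. Per the file layout, the score of each peak is the authors' rescaling of the IDR, with 1000 at the top. Thresholded lists begin at scores that correspond to an IDR of 0.01. The signal of each peak is the value from the authors' peak caller, and its normalization is not stated, so it was used only to rank and describe peaks within a list. By the column layout of such files, the deposited −log10 values are of the caller's adjusted p or q value in thresholded lists and of the global IDR in ranked lists. Every thresholded peak was found in the matching ranked list. The pooled ranked list held 1887 peaks at or above the lowest score of the series list, and 72 of these were not in it. Which list is pooled and which compares replicates was settled from the values: of the signals in the replicates' columns of the latter, 69.7% and 55.3% recur in the ranked list of 1 replicate each.

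Coordinates were compared with the reference genome WBcel235, whose chromosome lengths apply to ce11, and with the Ensembl annotation, release 115. The 6 nuclear chromosomes were used. A summit is the deposited peak offset added to the peak start. A gene was called bound when any summit lay within 1000 bp of its annotated 5′ end. All 19973 protein-coding genes served for distances, and the 19956 with a symbol were the background for gene lists. Each summit was classed by the annotation under it, with 5′ untranslated region, coding exon, 3′ untranslated region, intron and intergenic sequence in that order of precedence.

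Tests were run in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. Overlaps, positions and distances were compared with 1000 circular shifts of summits or peaks along their chromosomes, which keep the spacing of peaks, so the smallest p is 0.001. Chromosome shares were tested with exact binomial tests. Gene lists were compared with all other named genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 28 lists and a threshold of 0.05. Genes that share a divergent promoter share summits, so genes are not fully independent in these tests. Signal medians were compared with 100000 random reassignments. Intervals of shares are exact (Clopper-Pearson, 95%). Log2 odds had 0.5 added to each cell. A hexamer was counted on both strands in 101 bp at the summit and in flanking windows centred 300 bp away. The sign test planned before the data were seen set the centre against the mean of both flanks. Tested on random positions it called 1836 of 2080 hexamers, since a rare word is more often present in 2 windows than in 1. After its first result on the peaks had been seen, it was therefore replaced, and the centre was compared with 1 flank drawn at random per peak, which called 0 of 2080 on random positions. The log2 ratio still uses the mean of both flanks.

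The other tests were also checked on simulated data. Lists with 30% of their members bound were called in 50 of 50 simulations for the 101 homeobox genes and in 46 of 50 for the 30 pan-neuronal genes. Lists with no planted members were called in 7 of 800 tests. Each gene was drawn as bound independently in these simulations, so the rate of false calls where neighbouring genes share summits was not tested. The shift test for 5′ ends called 0 of 20 sets of the 1815 summits after a circular shift. It called 20 of 20 such sets with 10% of summits moved to 5′ ends. The sets without moved summits were made by the same kind of shift that the test uses, so few calls among them followed from their making. A TAATTA planted at 10% of centres ranked 1 among the 2080 hexamers. Those centres were random positions, not the GC-rich centres of summits, so detection at summits was not tested.

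Genes are named by a rule fixed before the data were examined: vab-7, the nearest gene of the 25 strongest peaks that have a 5′ end within 1000 bp, the 4 bound members of highest signal in each list that passed, and the 2 of highest signal in each other list. Also fixed then were the gene lists and the tests of replicate overlap and correlation, nearness to 5′ ends, the X chromosome, near and far signal, hexamers and gene lists. The tests of annotation classes, of the other chromosomes and of small RNA genes were not among them. Alternatives were the conservative list, either replicate's list alone, the upper 50% of peaks by signal, distances of 500 and 2000 bp, other overlap rules, other windows and flanks for hexamers, assignment to the nearest 5′ end only, ranked peaks outside the series list as background, and 10000 random gene lists matched on the upstream gap. The share of 5′ ends as background for the X chromosome was planned beside the test against length. Other alternatives were chosen after seeing the data. These left out summits within 200 bp of tRNA, snoRNA or snRNA genes, or kept only top scores. They also kept only peaks overlapped by both replicates' lists, or took a background of 10747 genes with a class symbol.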

Results

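The data describe chromatin recovered with an antibody against GFP from whole *Caenorhabditis elegans* larvae at the L4 stage, 47 hours of age. These larvae carried an EGFP-tagged VAB-7 protein. Whether the signal at a peak depends on that protein was not tested, since the control was not analysed here. VAB-7 is the nematode member of the Even-skipped class of homeodomain transcription factors, known for its roles in posterior patterning and in the identity of DB motor neurons. The tagged allele was made at the native vab-7 locus, and chromatin was precipitated with an antibody against GFP. There was 1 group of 2 biological replicates, so no condition was compared with another. Each replicate had its own list of peaks, with 1014 peaks for replicate 1 and 1119 for replicate 2. The list for the whole series held 1815 peaks, called the series list here, and a more conservative list held 1732. Peaks of the series list had a median width of 304 bp and covered 491 kb in all. The number of reads is unknown, because the lists carry no counts, so intervals below cover only the sampling of peaks or genes.

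The first question was whether the replicates gave the same regions. Of the 1014 peaks of replicate 1, 708 overlapped a peak of replicate 2 by at least 1 bp, which is 69.8% (exact 95% interval 66.9% to 72.6%). In the other direction 707 of the 1119 peaks of replicate 2 overlapped replicate 1 (63.2%). Circularly shifted lists overlapped in 0.606% of cases on average, and the one-sided permutation p of 0.001 was the smallest that 1000 shifts can give. Peaks at rpl-3, rpl-15 and rpl-35, genes for proteins of the large ribosomal subunit, were among the 699 series peaks overlapped by both replicates' lists. The median signal of these 699 peaks was 176, compared with 100.7 for the 245 peaks overlapped by replicate 1 alone, 102 for the 319 overlapped by replicate 2 alone and 79.8 for the 552 overlapped by neither. Over all 82859 peaks ranked in both replicates, Spearman's rho between the replicates' signals was 0.256. It was 0.663 over the 1732 peaks of the conservative list, 0.605 over the 1805 peaks of the series list found among the 82859 and -0.0641 over the upper 50% of ranked peaks by mean rank. The conservative list matches the ranking that compares the replicates and the series list the pooled one, and how far either selection moves rho was not tested. These are correlations across peaks, which are not independent replicates.

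The vab-7 gene itself (chromosome III, 10920344 to 10926041 in ce11, plus strand) had no summit of the series list within 1000 bp of its 5′ end. The nearest summit of the series list lay 2476 bp upstream, in intergenic sequence, in a peak from 10917716 to 10918019. Its signal of 89.8 ranked 1195 in the list, and it overlapped a peak of replicate 2 but none of replicate 1. The pooled ranked list held summits below the threshold 96 bp (signal 40.04, score 115) and 758 bp (signal 25.1, score 106) upstream of the 5′ end. A stronger one lay 1526 bp downstream (signal 61.5, score 70). That list holds 88007 peaks over 25504 kb, so such summits are common and do not show binding at the 5′ end.

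The highest signal of the series list, 697, was at a peak 271 bp upstream of rpl-3 (chromosome III, 3867437 to 3867694). Peaks upstream of K12H4.5 (643), tasp-1 (583), mtcu-2 (545) and eel-1, which encodes a HECT-type ubiquitin ligase (519), and downstream of the 5′ end of K08F11.1 (533), followed among peaks within 1000 bp of a 5′ end, to which this account is limited. The peak of mog-4, an RNA helicase gene of pre-mRNA splicing, had a signal of 519, that of rpl-15 had 477, and that of cdc-48.1, which encodes an AAA ATPase of protein degradation, had 474. The next signals of such peaks, from 449 to 399, belonged to rpa-2, a replication protein A subunit gene, Y17G9B.5, rpl-35, dnj-28, nlp-4 and atad-3. The peak assigned to Y17G9B.5, from 4749966 to 4750184 on chromosome IV, also lay 309 bp upstream of rpl-20, which is transcribed the other way. The remaining genes named by the 25 strongest peaks near a 5′ end were rps-24 (369), twk-5 (360), nspc-17 (352), F44E5.4 (348), Y75B12B.11 (337), ears-2 (333), egl-17 (322), C01C4.3 (320), mdt-26 (317) and cox-5B (317). All 25 peaks overlapped peaks of both replicates. Peaks farther from a 5′ end reached similar signals, for example 519.7 on chromosome IV (4727918 to 4728145) and 469 at a tRNA gene on the X chromosome (3035948 to 3036287), both picked after their values were seen. Those of nlp-4, twk-5 and Y75B12B.11 had a summit within 200 bp of a snoRNA gene, and those of egl-17, a fibroblast growth factor gene, and C01C4.3 within 200 bp of a tRNA gene.

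Summits lay in intergenic sequence and near the 5′ ends of protein-coding genes more often than shifted summits did. The classes are those of protein-coding genes, so a summit inside a tRNA gene counts by the protein-coding annotation around it. Intergenic positions held 1064 of the 1815 summits (58.6%, exact 95% interval 56.3% to 60.9%), where shifted summits gave 36.8% on average. Coding exons held 6.83% compared with 24.1% for shifted summits, 3′ untranslated regions 1.10% compared with 3.39%, and introns 30.1% compared with 33.9%. The 5′ untranslated regions held 3.36% compared with 1.76%. All 5 places passed a two-sided permutation test over 1000 shifts, with Benjamini-Hochberg adjusted p between 0.00125 and 0.005. Within 1000 bp of a 5′ end lay 894 summits, 49.3% (46.9% to 51.6%) compared with 33.9% for shifted summits (two-sided permutation test, p = 0.001, the smallest the shifts can give). Of these, 640 were upstream and 254 downstream, with a median position of -166.5 bp, and this division was not tested against shifts. Signal did not differ detectably between the 894 near and the 921 far summits: the medians differed by -0.02 on the log2 scale (two-sided permutation test, p = 0.513). Many *C. elegans* genes lie in operons or are trans-spliced, so an annotated 5′ end is not always where transcription starts.

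**Figure D1:**
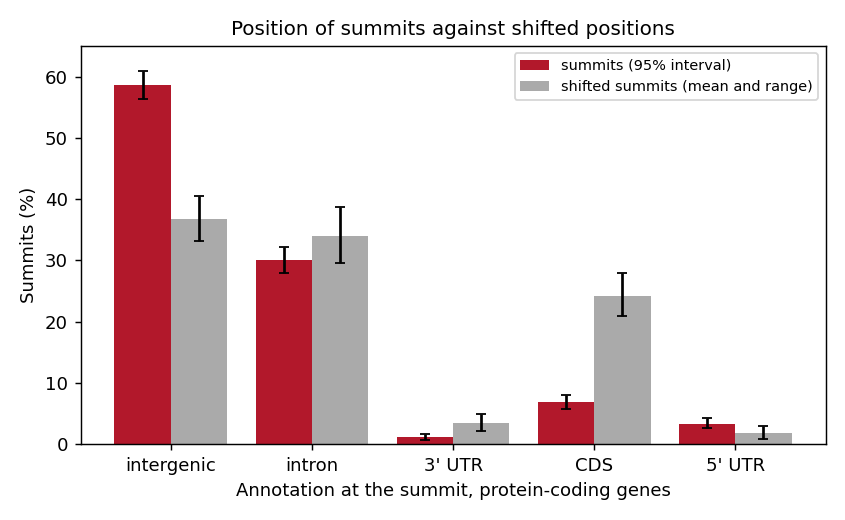
Share of the 1815 summits (vertical axis, percent) in each annotation class of protein-coding genes (horizontal axis), with exact 95% intervals, beside the mean and range of 1000 circular shifts in grey. Intergenic sequence holds 58.6% of summits and 36.8% of shifted ones, coding sequence 6.83% and 24.1%.

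Most annotated tRNA genes had a summit. Of the 612 annotated tRNA genes, 446 had a summit within 200 bp of their 5′ end (72.9%, exact 95% interval 69.2% to 76.4%). These sites took 418 of the 1815 summits, where shifted summits gave 4.53 on average, and 330 of the 418 summits lay inside the tRNA gene. The share of peaks with a summit at a tRNA gene was 23.03% in the series list. It was 30.3% in replicate 1's list, 31.3% in replicate 2's and 0.0882% among the 86192 ranked peaks outside the series list. Small nucleolar RNA genes took 75 summits (2.48 for shifted ones), at 75 of the 346 annotated genes, and small nuclear RNA genes took 22 (0.796 for shifted ones). Summits at tRNA genes had a median signal of 151, compared with 98.04 elsewhere, a difference of 0.63 on the log2 scale (two-sided permutation test, p = 1e-05, the smallest 100000 resamples can give). The comparisons with small RNA genes were chosen after the tRNA summits had been seen.

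The X chromosome and chromosomes I and III held more summits than their lengths give, and chromosomes IV and V fewer. The X chromosome held 386 summits, 21.3% (exact 95% interval 19.4% to 23.2%), for 17.7% of genome length and 13.7% of protein-coding genes. Two-sided exact binomial tests gave an adjusted p of 0.000183 against length and of 3.01e-18 against the share of genes. Chromosome III held 18.1% for 13.7% of length (exact binomial test, adjusted p = 5.23e-07), and chromosome V 14.2% for 20.9% (adjusted p = 2.13e-12). Chromosome I held 17.5% for 15.03% (exact binomial test, adjusted p = 0.00511), chromosome IV 14.7% for 17.4% (adjusted p = 0.00239) and chromosome II 14.3% for 15.2% (adjusted p = 0.267). The X chromosome also carries 276 of the 612 tRNA genes, and 192 of its 386 summits lay at tRNA genes. Away from tRNA genes its share was 13.9%, below its share of length (exact binomial test, p = 0.00015). The direction against length thus turned when these summits were left out. The 13.9% lay near the chromosome's 13.7% of protein-coding genes, a comparison that was not tested.

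**Figure D2:**
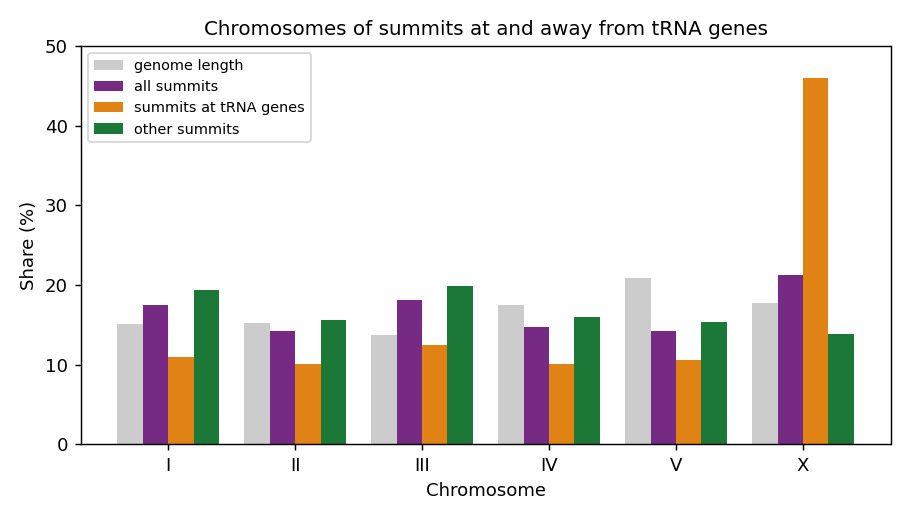
Share (vertical axis, percent) of genome length, of all 1815 summits, of the 418 summits within 200 bp of a tRNA gene and of the other 1397 summits on each of 6 chromosomes (horizontal axis). The X chromosome has 45.9% of the summits at tRNA genes and 13.9% of the others.

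Homeodomains of the Even-skipped class are known to bind TAAT cores, so the words TAATTA and TAATGA were counted on both strands within 50 bp of each summit and in 2 flanking windows of the same size centred 300 bp away. The words were fewer at summits: 80 occurrences compared with a mean of 220 in a flank, a log2 ratio of -1.45. Of the 1815 peaks, 71 had more words at the summit than in a flank drawn at random and 209 had fewer (two-sided exact sign test, p = 6.06e-17). At least 1 word was present in 4.30% of central windows and in 11.5% and 11.1% of the left and right flanks. Central windows had a GC content of 49.7%, compared with 35.9% and 35.5% in the flanks. Of all hexamers, 725 were more frequent at summits and 487 less frequent at an adjusted threshold of 0.05. By the exact sign test, ACCACT (log2 ratio 2.33, Benjamini-Hochberg adjusted p = 1.24e-38) and CGAACC (2.35, adjusted p = 6.03e-36) had the smallest p among the former. CGAACC is the reverse complement of GGTTCG, which is part of the B box, the internal promoter element of tRNA genes. Without summits at tRNA genes, GCGCGC came first (log2 ratio 3.86, adjusted p = 4.95e-33) and the TAAT words still had a log2 ratio of -1.29 (exact sign test, p = 1.48e-09). Set against the count expected from each window's own base composition, the TAAT words were observed at 0.557 of that count in central windows and 0.517 in flanks, a log2 ratio of 0.11 (bootstrap 95% interval -0.26 to 0.42), so no deficit at summits was detectable after this correction. The other hexamers, ACCACT, CGAACC and GCGCGC included, were not corrected in this way. Whether any of them exceeds what the GC content of central windows gives was not tested.

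A total of 1099 of 19956 named protein-coding genes had a summit within 1000 bp of the 5′ end (5.51%), and these are called bound below. The word refers to the position of summits only, and dependence on the tagged protein was not tested for any list. Genes for ribosomal proteins were bound far more often than other genes: 48 of 81, 59.3% (exact 95% interval 47.8% to 70.1%) compared with 5.29% (two-sided Fisher's exact test, adjusted p = 3.57e-38 over 28 lists). The 4 strongest were rpl-3, rpl-15, rpl-20 (443) and rpl-35 (433). The 48 genes had 44 different strongest summits, that of 4 genes lay at a snoRNA gene, and 20 of the 48 genes had a peak overlapped by both replicates' lists. With the list of replicate 1 alone 30 of the 81 were bound (37.04%, compared with 2.97% of other genes), and with that of replicate 2 alone 26 (32.1%, compared with 3.33%). The conservative list had 36 of the 81 bound (44.4%, compared with 4.98%), with log2 odds of 3.94 in place of 4.70. Heat shock protein genes followed with 7 of 20 (35.0%, Fisher's exact test, adjusted p = 0.000347), including hsp-60, the mitochondrial chaperonin gene (signal 271), hsp-1 (241) and hsp-3 (189), genes of constitutive Hsp70 chaperones, and hsp-90 (143). In the conservative list 4 of the 20 were bound, with log2 odds of 2.34 in place of 3.26, and the adjusted p of Fisher's exact test was 0.0694.

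Histone genes were bound in 12 of 50 cases (24.0%, Fisher's exact test, adjusted p = 8.88e-05), among them his-37 (241), his-60 and his-59, which share a peak with a signal of 129.3, and his-61 (96.3). Neighbouring histone genes shared summits, and the 12 genes had 7 different ones. With the list of replicate 2 alone 5 of the 50 were bound (log2 odds 1.77 in place of 2.49, Fisher's exact test, adjusted p = 0.113), and likewise 5 with the list of replicate 1 alone (log2 odds 1.92, adjusted p = 0.0891). In the conservative list 12 were bound (Fisher's exact test, adjusted p = 5.67e-05). Genes of the respiratory chain were bound in 7 of 43 cases (16.3%, Fisher's exact test, adjusted p = 0.0341), including cox-5B (317), cox-5A (304) and cox-6A (182, at a snRNA gene), genes for subunits of cytochrome c oxidase, and atp-1 (201), a subunit gene of the ATP synthase. This call was lost in the conservative list (5 of 43, log2 odds 1.40 in place of 1.82, Fisher's exact test, adjusted p = 0.212) and in a permutation test against random lists matched on the gap upstream of each gene (adjusted p = 0.195). It passed with the list of replicate 1 alone (7 of 43, Fisher's exact test, adjusted p = 0.00184) and of replicate 2 alone (6 of 43, adjusted p = 0.0188). Heterochronic genes, which time larval development, were bound in 4 of 13 cases (30.8%, exact 95% interval 9.09% to 61.4%, Fisher's exact test, adjusted p = 0.0204). They were nhl-2 (313), lin-46 (150), lin-66 (133) and lin-28 (91.5), with summits between 344 and 837 bp from the 5′ ends. With the list of replicate 1 alone 2 of the 13 were bound (15.4% compared with 3.10% of other genes, log2 odds 2.76 in place of 3.03, Fisher's exact test, adjusted p = 0.24), and within 500 bp 1 of them (adjusted p = 0.854). In the conservative list 5 were bound (log2 odds 3.58, Fisher's exact test, adjusted p = 0.0018).

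**Figure D3:**
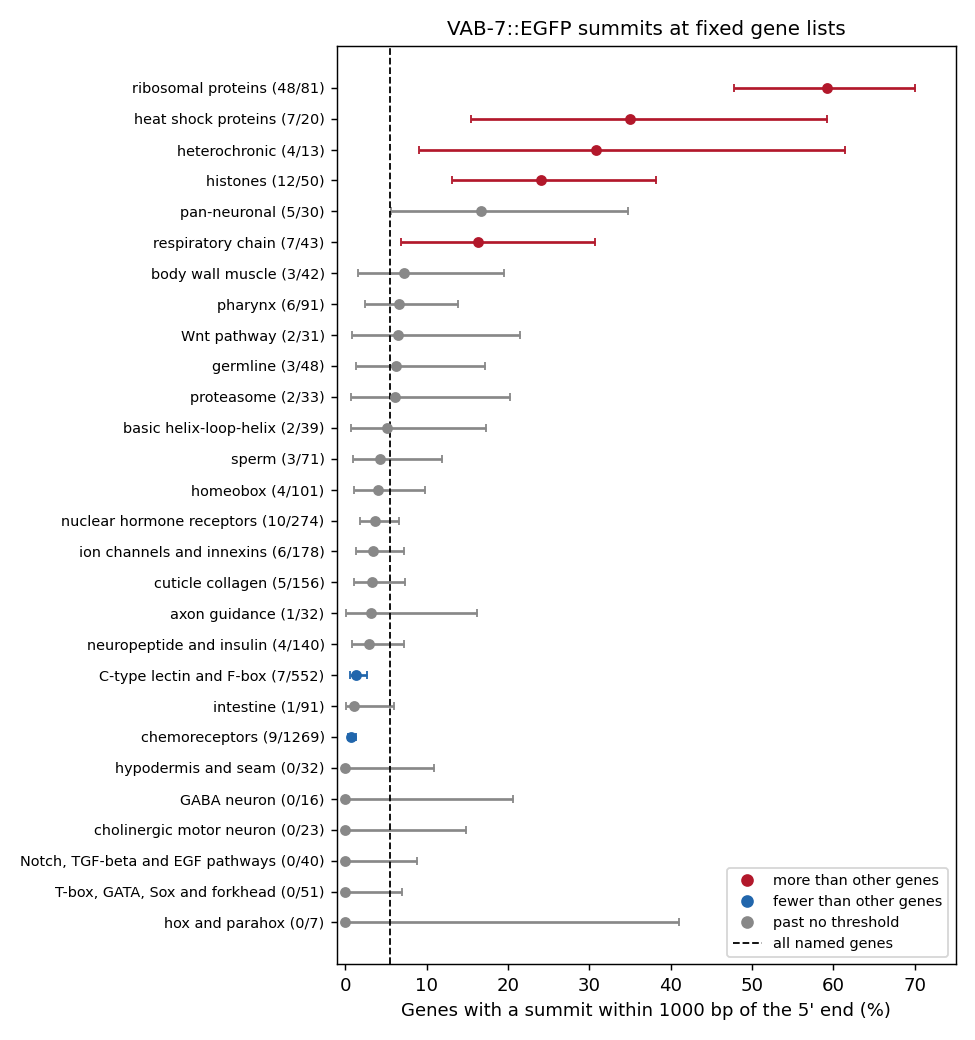
Share of the genes of each of 28 fixed lists with a summit within 1000 bp of the 5′ end (horizontal axis, percent) and exact 95% intervals, with the number bound over the number in the list beside its name. The dashed line marks the 5.51% of all named genes. Ribosomal protein genes, at 59.3%, lie farthest above it.

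Chemoreceptor genes, and C-type lectin and F-box genes, were bound less often than other genes. Of 1269 chemoreceptor genes 9 were bound, 0.709% compared with 5.83% (Fisher's exact test, adjusted p = 4.42e-20), and 4 of these 9 had their strongest summit at a tRNA gene. The highest signals were at sre-23 (315, at a snoRNA gene), srh-269 (282) and srv-16 (167), both at tRNA genes, and srbc-38 (155). C-type lectin and F-box genes were bound in 7 of 552 cases, 1.27% compared with 5.63% (Fisher's exact test, adjusted p = 3.23e-06), with fbxb-58 (294), clec-126 (176, at a tRNA gene), fbxb-85 (122) and fbxa-90 (100.7) the strongest. With the list of replicate 1 alone 1 of the 552 was bound, and with that of replicate 2 alone 6.

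Lists of developmental regulators and of neuronal genes passed no threshold, apart from the heterochronic genes. None of the 7 Hox and ParaHox genes, the 23 cholinergic motor neuron genes, the 16 GABA neuron genes, the 32 genes of hypodermis and seam, the 40 genes of the Notch, TGF-beta and EGF pathways or the 51 T-box, GATA, Sox and forkhead genes was bound (Fisher's exact test, adjusted p from 0.324 to 1). Intervals for these shares reached from 6.98% for the 51 transcription factor genes to 41.0% for the Hox and ParaHox genes, all above the 5.51% of all genes, so lower binding was not detectable at these list sizes. Of all homeobox genes, the Hox and ParaHox genes included, 4 were bound (3.96%, Fisher's exact test, adjusted p = 0.895), the strongest being ceh-38 (166) and ceh-2 (131, at a tRNA gene). Pan-neuronal genes had 5 of 30 bound (16.7%, exact 95% interval 5.64% to 34.7%, Fisher's exact test, adjusted p = 0.0794), led by unc-11 (100) and unc-36 (90.9). The share passed the test within 2000 bp (8 of 30, Fisher's exact test, adjusted p = 0.0103), while 1 of the 30 was bound with replicate 2's list alone and 0 with replicate 1's.

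In the remaining lists the bound share was not distinguished from other genes, with adjusted p of Fisher's exact test from 0.199 to 1. They included 10 of 274 nuclear hormone receptor genes (nhr-255 at 205, beside a tRNA gene, and nhr-47 at 128), 2 of 39 basic helix-loop-helix genes (hlh-11 at 99.1 and mml-1 at 79.9), 2 of 31 Wnt pathway genes (mig-5 at 85.7 and wrm-1 at 81.6) and 1 of 32 axon guidance genes (unc-40 at 85.8). Among tissue markers, 3 of 42 body wall muscle genes (act-2 at 97.98 and unc-60 at 88.3), 1 of 91 intestine genes (ugt-12 at 78.3), 3 of 48 germline genes (mex-1 at 248 and puf-9 at 168) and 3 of 71 sperm genes (spe-15 at 179.9, beside a tRNA gene, and spe-48 at 116) were bound. The intestine list takes in every gene with a ugt symbol and the germline list every gene with a puf symbol. Both ugt-12 and puf-9 entered by symbol alone, so they say little of those tissues. The list fixed for the pharynx takes in every gene with a pqn symbol, given to proteins rich in glutamine and asparagine, and its 6 bound members of 91 were all pqn genes (pqn-71 at 236, beside a tRNA gene, and pqn-51 at 227), so it says little of pharynx markers. Other counts were 4 of 140 neuropeptide and insulin genes (nlp-4 at 411 and ins-39 at 169), 5 of 156 cuticle collagen genes (col-85 at 301 and col-185 at 228, both at tRNA genes), 2 of 33 proteasome genes (pbs-3 at 111 and rpn-3 at 82.1) and 6 of 178 ion channel and innexin genes (twk-5 at 360 and twk-48 at 213). Of the last 6 genes, 5 had their strongest summit at a tRNA gene and 1 at a snoRNA gene.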

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

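The comparison of small RNA genes with shifts, the test of signal at active loci and the settings without summits at tRNA genes were chosen after summits at tRNA genes had been seen, and the remaining tests of explanations were chosen after the patterns but before their own results were seen. The design has 1 group, so no explanation that rests on a difference between groups was tested. Of those that involve the tagged protein, recruitment by TAAT words was examined at tRNA genes, without correction for base composition.

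The ranked list of the pooled replicates holds signal that the series list leaves out. The strongest of the peaks left out, on the X chromosome from 15810939 to 15811210, has a signal of 3392.63 (3393 rounded), is intergenic and lies 6934 bp from the nearest protein-coding 5′ end. In all 72 peaks at or above the lowest score are left out, and 3 of them exceed the highest signal of the series list, 697. Summits also lie at small RNA genes, which the planned comparisons did not use: 418 within 200 bp of a tRNA gene, 75 of a snoRNA gene, 22 of a snRNA gene and 11 of a miRNA gene, each above the most seen in 1000 shifts (15, 10, 4 and 10).

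Among tRNA genes, 72.9% had a summit. Of 143 tRNA genes with a sequence found once among annotated tRNA genes, 53.8% had a summit (exact 95% interval 45.3% to 62.2%). The share was 78.7% of 469 genes with identical copies, and a part of that excess may come from shared reads. Fully identical annotated copies therefore do not account for the pattern as a whole. Genes that differ by a few bases counted as found once, and the aligner is unknown. Reads shared between near-identical copies were thus not tested and stay open. GC content alone does not either, since 2.21% of 12240 windows of equal GC content away from tRNA genes had a summit. TAAT words beside the genes were less common at tRNA genes with a summit than at those without (27.8% and 45.2%, log2 odds ratio -1.10, interval -1.65 to -0.54). Recruitment by these words predicted the opposite direction. Base composition beside the genes was not corrected for, so the comparison does not decide on recruitment. Signal at active loci that does not need the tagged protein also stays open, as does binding of VAB-7 at these genes. Ribosomal protein genes were also bound often (59.3%, or 32.1% to 37.04% with 1 replicate's list), and an untagged control was not analysed here.

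The X chromosome's share of summits was 21.3%, above its 17.7% of genome length. It carries 276 of 612 tRNA genes, and without summits at tRNA genes its share was 13.9% (exact 95% interval 12.1% to 15.8%). The excess over length goes with the location of tRNA genes. Away from them the X share lay below its length share and near its 13.7% of protein-coding genes.

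TAAT words were fewer at summit centres. The sequence of tRNA genes does not account for this alone, because without those summits the log2 ratio was -1.29. The base composition of the central windows is a candidate explanation: against the count expected from each window's own bases, the ratio of centre to flank was 0.11 on the log2 scale (bootstrap 95% interval -0.26 to 0.42), with 80 words observed and 143.6 expected at centres (ratio 0.557) and 440 observed and 851 expected in both flanks (ratio 0.517). Relative to the flanks, a deficit beyond base composition was not detectable within that interval.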

How the results depend on the processing

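Alternatives at small RNA genes, top scores, peaks overlapped by both replicates' lists and class symbols were chosen after seeing the data. The limit at an IDR of 0.01 removes no peak and was not run. The share of summits near a 5′ end and the overlap of replicates kept their direction and their side of the threshold under every alternative run. The deficit of TAAT words did so under the other peak lists, subsets of peaks, windows and flanks, but not after correction for base composition, where the log2 ratio of -1.45 went to 0.11 (interval -0.26 to 0.42). The near and far signal difference passed no threshold under any, though its sign varied. The number of peaks was 1014 to 1119 in lists of 1 replicate, 907 in the upper 50% by signal and 699 with both replicates' lists. The log2 ratio of the X share to its length share was 0.27. It was 0.54 with replicate 2's list alone and 0.32 with replicate 1's alone. In the conservative list it was 0.24, and in the upper 50% by signal 0.53. It turned to -0.35 without summits at tRNA genes and to -0.26 without those at tRNA, snoRNA and snRNA genes. Of the summits at tRNA genes, 45.9% are on the X chromosome. Spearman's rho of 0.256 moved to 0.663 over the conservative list, to 0.605 over the series list and to -0.0641 over the upper 50% by mean rank, where choosing by the mean of both ranks works against a correlation. The conservative list was thresholded on the ranking that compares these same replicates, so its rho is not independent of that choice. How far selection raised either of the higher values was not tested. Of the 28 lists 7 passed, 4 did with peaks overlapped by both replicates' lists, where fewer peaks enter, and 9 did without summits at tRNA genes and also without those at tRNA, snoRNA and snRNA genes. Ribosomal protein, chemoreceptor, and C-type lectin and F-box genes passed in 13 of 13 alternatives, heat shock in 12, histone in 9, and respiratory chain and heterochronic genes in 8 each. Of 364 values of single lists, 343 kept their side of the threshold, 15 lost a call and 6 gained one, and no called list reversed. Read depth is unknown, so its effect could not be assessed.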

Other observations

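Ion channel and innexin genes had 6 of 178 members bound, 5 of them with their strongest summit at a tRNA gene. Without summits at tRNA genes, an alternative chosen after seeing the data, 1 of the 178 was bound (0.562% compared with 4.90% of other genes, Fisher's exact test, adjusted p = 0.0111), a fall that the place of those 5 summits fixes beforehand. Pan-neuronal genes had 5 of 30 bound with and without these summits. Their adjusted p went from 0.0794 to 0.0433 (Fisher's exact test) as the share of other genes bound went from 5.49% to 4.84%. The 5 were unc-11, unc-36, egl-3, ehs-1 and ida-1, the last 3 named after their values were seen, and their signals ranged from 72.5 to 100.3. None of the 5 had a summit within 1000 bp in a peak overlapped by both replicates' lists.

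Genes for piRNAs had fewer summits within 200 bp than shifted positions gave: 10 summits at 15363 genes compared with 50.1 on average (two-sided permutation test, adjusted p = 0.00167). Genes annotated as other ncRNA had 440 compared with 49.5 (adjusted p = 0.00167, permutation test), and how many of these lie beside tRNA genes was not counted. Pseudogenes had 18 compared with 13.7 (permutation test, adjusted p = 0.406). None of the 1815 summits lay at the 20 annotated rRNA genes, where shifts gave 0.108. However, the 72 peaks left out of the series list included some at rRNA genes, for example rrn-4.2 (signal 166) and rrn-4.5 (86.7). The absence therefore holds for the series list only. Peaks at tRNA genes overlapped both replicates' lists in 62.9% of cases, compared with 31.2% of all other peaks, and those at snoRNA genes in 66.7%, compared with 37.3% of all other peaks.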
